A study of Mus musculus with 6 samples.

How the data were processed

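Polyadenylated RNA from 6 samples of HL-1 cells was sequenced as paired-end reads from a stranded library kit, per the labels' protocols. In the labels 3 samples carry a control plasmid and 3 an HSPA1A overexpression plasmid, both introduced with a lipid transfection reagent and harvested after 48 h. The groups and the replicate numbers 1 to 3 were taken from the labels. The submitters' processing notes name bcl2fastq, TopHat2, edgeR and the mouse build GRCm38, without versions or roles. The read counter, its strand setting and the annotation release are not given in the sources used here.

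The authors deposited a table of whole read counts per gene, with 22913 genes that have at least 1 read in some library, and a table of FPKM for 22833 of these genes, which is scaled by gene length and library size per the file headers and the values. The FPKM values were rounded by the authors, so low levels are coarse. Both tables hold 1 column per sample, and 0 columns were left unused. Gene coordinates came from the GENCODE M21 annotation of GRCm38, in which 22729 of the gene identifiers were found. Because counts rest on alignment to the mouse genome, a transcript of a human plasmid is counted only as far as its reads align to mouse genes, and near-identical genes such as Hspa1a and Hspa1b can exchange reads.

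The depth was 26445340, 24540652 and 26090167 counts in control replicates 1 to 3 and 23849656, 26897086 and 24849547 counts in HSPA1A replicates 1 to 3. The libraries were normalised by TMM in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 12827 genes. The groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05, without covariates. The biological coefficient of variation was 0.0688. CPM values printed as mean ± SD are CPM scaled by TMM. For Hspa1a, Hspa1b and their sum, exact two-sided permutation tests of log2 CPM were run.

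The fit was tested on simulated counts for the HSPA1A and control comparison over 12827 genes, with 200 changed genes in each of 3 runs. It called 77.0% of genes changed by 1.5-fold, 91.1% at 2-fold, 97.3% at 3-fold and 99.3% at 4-fold, and 0.0799% of the unchanged genes. The simulated genes were drawn independently at the trended dispersion, without a library that stood apart, so these rates may not hold for the real libraries.

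Before the data were examined, 28 gene lists, the tests, most alternatives and the rule for named genes were fixed. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation and with fry. The rule named Hspa1a and Hspa1b, up to 12 called genes in each direction with the largest change, a mean of at least 5 CPM and no overlap of the groups, up to 4 called genes of each list by p or up to 2 uncalled ones as values only, and Nppa, Nppb, Myh6, Myh7 and Acta1. Names made of clone identifiers were left out. Other genes were named after their values were seen, such as list members called over the list alone or without HSPA1A replicate 2. This is not stated at each of them. Of the tested genes, 14.5% had no overlap between the groups, where chance gives 10%.

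The alternatives were DESeq2-type size factors, library totals alone, normalisation without Hspa1a and Hspa1b, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 5 CPM in 3 libraries, the replicate number as a block, each library left out in turn, a 2-fold minimum, and limma-trend on log2 of the deposited FPKM plus a pseudocount of 1 or 0.1 or with a mean FPKM of at least 1. A correction for gene length and GC content with smooth terms in mgcv 1.9.3 and a fit with the log2 level of Yam1 as a covariate were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.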

Results

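Gene expression was measured by sequencing of polyadenylated RNA in HL-1 cells, a mouse line derived from atrial heart muscle cells. The cells received either a control plasmid or a plasmid for overexpression of HSPA1A, the inducible heat shock protein of the HSP70 family, and were harvested 48 h later. Each group held 3 libraries. The read counts per library summed to between 23849656 and 26897086, and 12827 of the 22913 genes listed had enough counts to be tested. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. No library was a copy of another, since every pair differed by more than counting noise, with chi-square values per degree of freedom from 2.78 to 28.1. On the first principal component of the log2 values, which held 34.3% of the variance, HSPA1A replicates 1 and 3 lay at 15.9 and 18.3. HSPA1A replicate 2 lay at -15.1 and the control libraries between -8.27 and -4.33.

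The first measurement was the level of the overexpressed gene itself. Mouse Hspa1a (ENSMUSG00000091971.3, chromosome 17, 34969190 to 34972156 on the minus strand of GRCm38) was low in both groups, at 0.491 ± 0.166 CPM in control and 0.640 ± 0.160 CPM in HSPA1A libraries (SD, n = 3 each). Its read counts were 10, 17 and 11 in the control libraries and 17, 20 and 11 in the HSPA1A libraries. The log2 fold change was 0.39, with a 95% interval from -0.38 to 1.16 and an adjusted p of 0.795 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out one library at a time gave log2 fold changes from 0.23, without control replicate 1, to 0.69, without control replicate 2, none past the threshold. The nearly identical neighbour Hspa1b stood at 2.79 ± 0.28 CPM in control and 2.97 ± 0.55 CPM in HSPA1A libraries (SD, n = 3 each). Exact two-sided permutation tests gave p = 0.2 for Hspa1a, p = 0.7 for Hspa1b and p = 0.5 for their sum, where 0.1 is the smallest p that 3 against 3 libraries allow. Reads can be shared between the pair, and Hspa1a overlaps Gm20481 on the other strand, so the split between these genes is uncertain. The labels call the transfected gene human, and reads were counted on mouse genes, so these values hold the plasmid's own transcript only as far as its reads align to mouse genes, which was not tested.

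The central comparison asked which genes differed between HSPA1A and control cells. Among inflammatory and NF-kB pathway genes, 9 were called lower, and each of these was lower in all 3 HSPA1A libraries than in any control library. The neutrophil-attracting chemokine gene Cxcl1 (ENSMUSG00000029380.11, chromosome 5, 90891241 to 90893115) fell from 177 ± 4.4 CPM to 51.6 ± 7.6 CPM (SD, n = 3 each), 3.44 times lower, with a log2 fold change of -1.78 ± 0.09 (SE). Cxcl5 (chromosome 5, 90759360 to 90761624), another neutrophil chemokine gene, fell from 33.18 ± 3.53 to 12.01 ± 1.36 CPM, 2.77 times lower. The monocyte-attracting chemokine genes Ccl2 and Ccl7 were 2.20 and 2.13 times lower, at 12.3 ± 0.5 and 12.5 ± 1.5 CPM in HSPA1A against 27.1 ± 2.4 and 26.6 ± 2.8 CPM in control libraries. The complement component gene C3 was 2.62 times lower, and Lcn2, which encodes the iron-siderophore-binding protein lipocalin 2, was 3.27 times lower but varied more, at 21.5 ± 9.1 against 70.2 ± 12.8 CPM. Adjusted p-values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 1.93e-05 for Cxcl1, 0.000215 for Cxcl5, 0.000268 for Ccl2, 0.000425 for C3, 0.00133 for Ccl7 and 0.0192 for Lcn2. The NF-kB family genes Relb and Nfkb2 and the NF-kB cofactor gene Nfkbiz were lower by smaller amounts, with log2 fold changes of -0.70, -0.44 and -0.90. Nfkb2 was named after its values were seen, and it overlaps Psd on the other strand, as Ccl2 overlaps Gm17268. Whether the counting used strand is not given in the sources used here.

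These 9 genes made up all the called members of the fixed list of NF-kB and inflammatory genes, of which 38 were tested. None of the 38 was called higher, and 15 were lower when p-values were adjusted over the list alone. The further 6 were Ccl5, Nfkbia, Bcl3, Saa3, Csf1 and Lif. The list's median log2 fold change was -0.33, and camera called it lower with the preset correlation of 0.01 (adjusted p = 1.01e-60) and with an estimated correlation (adjusted p = 0.0122). The median was -0.18 without HSPA1A replicate 1 and -0.20 with the level of Yam1 as a covariate, and the list was still called in both. Yam1 is a noncoding transcript that overlaps an annotated ribosomal RNA gene on the other strand. With that covariate Relb, Nfkb2 and Lcn2 were no longer called, at log2 fold changes of -0.66 ± 0.11, -0.45 ± 0.08 and -1.88 ± 0.37 (SE). Of the 20 genes lower in HSPA1A cells, 9 came from this list, against 0.0593 by the share of the list among the tested genes (one-sided Fisher's exact p = 1.04e-18). Fisher's test treats the genes as independent and does not measure the spread between libraries.

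In all, 3 genes were called higher and 20 lower in HSPA1A cells at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 7 of the lower and 0 of the higher genes differed by at least 2-fold. At an unadjusted p under 0.05 there were 556 genes higher and 546 lower, 1102 in all against 641 expected by chance. The higher genes were Maoa, which encodes monoamine oxidase A, and the interferon-induced genes Ifi44 and Ifi27l2a. Maoa stood at 115 ± 1.6 CPM in HSPA1A and 88.9 ± 1.4 CPM in control libraries (SD, n = 3 each; log2 fold change 0.37). Ifi44 rose from 34.1 ± 4.0 to 50.4 ± 4.3 CPM and Ifi27l2a from 45.0 ± 4.8 to 65.4 ± 5.9 CPM. Among the lower genes outside the inflammatory list, Zc3h12a, which encodes an RNase that degrades cytokine mRNAs, fell from 17.8 ± 0.4 to 9.21 ± 0.64 CPM. The transcription factor gene Cebpd fell from 15.03 ± 3.19 to 7.57 ± 1.06 CPM and overlaps Spidr on the other strand. Col8a1, which encodes a short-chain collagen, fell from 69.9 ± 0.9 to 39.8 ± 4.1 CPM, and Ntn1, which encodes the guidance cue netrin 1, from 21.7 ± 2.1 to 14.6 ± 0.3 CPM. The stress-response gene Ier3 fell from 165 ± 5.4 to 127 ± 7.7 CPM. The other lower genes were named after their values were seen. Slc11a2, an iron transporter gene, Casp4, an inflammatory caspase gene, Itpripl2, Cd34 and Dhrs1 had log2 fold changes from -0.56 to -0.39. Slc11a2, Ntn1 and Cd34 also overlap genes on the other strand. Hp, which encodes haptoglobin, had 74 reads over the control libraries and 8 over the HSPA1A libraries, a mean of 0.526 CPM.

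**Figure D1:**
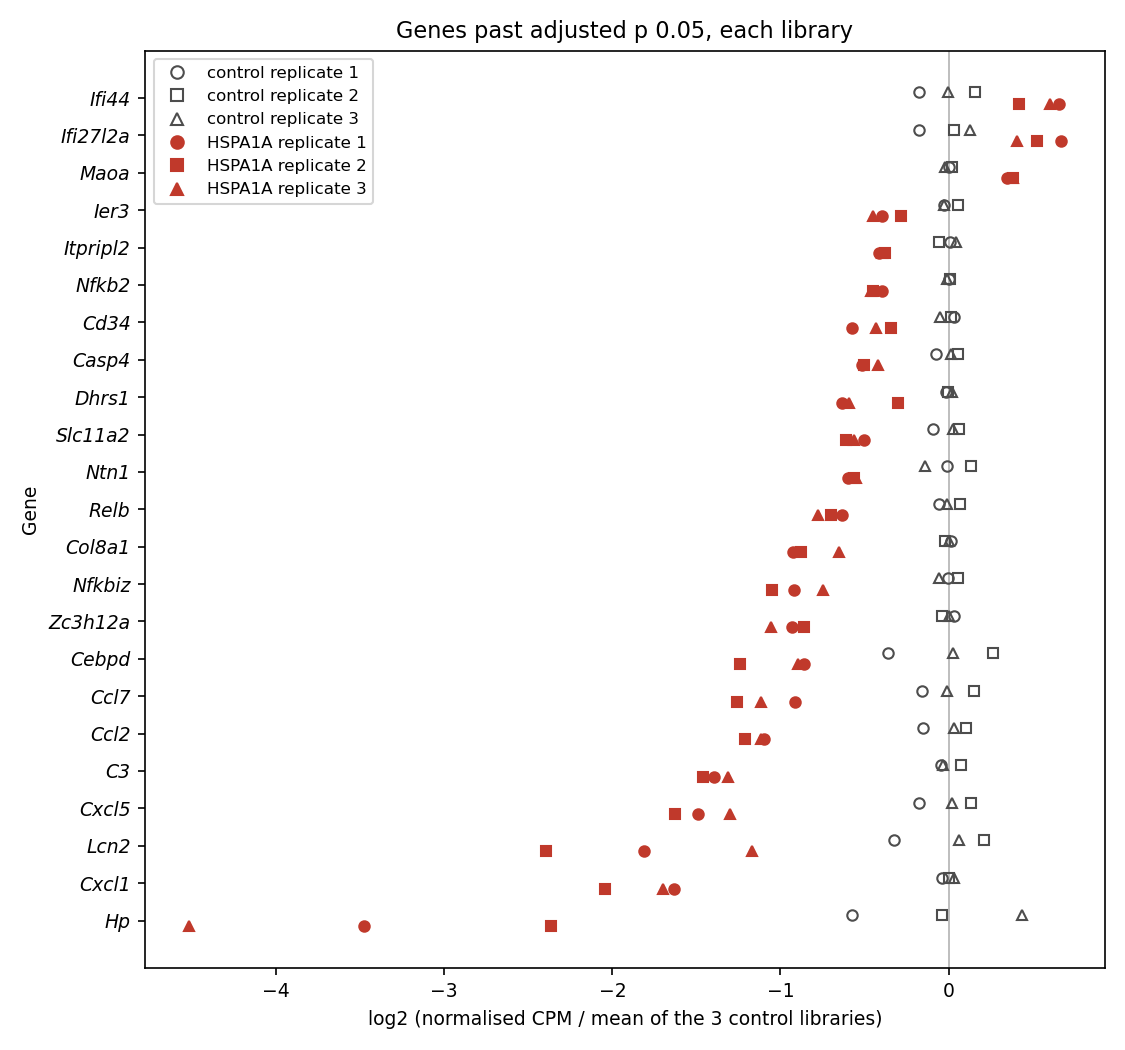
Log2 ratio of normalised CPM to the mean of the 3 control libraries (x axis) for the 23 genes past an adjusted p of 0.05 (y axis). Each point is 1 library, open for control and filled for HSPA1A, with a shape for each replicate; for all 23 genes the 3 HSPA1A points lie on one side of the 3 control points, and 20 of the 23 genes are lower.

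The number of genes called rested on single libraries. Without HSPA1A replicate 2, 683 genes were higher and 640 lower. Leaving out control replicate 1, 2 or 3 or HSPA1A replicate 1 or 3 gave totals of 14, 13, 10, 13 and 14. All 23 genes stayed called without HSPA1A replicate 2. Cxcl1, Cxcl5, Ccl2, C3, Nfkbiz, Col8a1, Zc3h12a, Ccl7, Relb and Slc11a2 stayed called in all 6 such fits, and the other 13 genes lost the call in at least 1. Lcn2 lost it without control replicate 2, control replicate 3 or HSPA1A replicate 1, Nfkb2 without control replicate 3, and Casp4 without control replicate 2 or 3. Maoa lost it without any one of the controls, with adjusted p-values up to 0.171 in edgeR's quasi-likelihood test, and Ifi44 without control replicate 1 or 3 or HSPA1A replicate 1 or 3. Cebpd lost it without control replicate 2 or 3 or HSPA1A replicate 1 or 3, and Itpripl2 without control replicate 1 or 3 or HSPA1A replicate 1 or 3. Ifi27l2a, Ntn1, Cd34, Ier3, Dhrs1 and Hp were called in 1 of the 6 fits, the one without HSPA1A replicate 2. DESeq2 called 27 genes higher and 41 lower, including all 23, and with no filter on low counts edgeR called 94 higher and 111 lower.

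Of the 28 gene lists fixed beforehand, 27 had at least 5 tested members, and camera with the preset correlation called 6 higher and 3 lower. Interferon-stimulated genes, which respond to viral or foreign nucleic acid, shifted upwards, with a median log2 fold change of 0.16 over 50 genes (adjusted p = 1.19e-10). With an estimated correlation the list was not called (adjusted p = 0.404), nor was it with fry (adjusted p = 0.245). Of its members, Ifi44 alone was called over all genes, while 7 were higher and none lower when adjusted over the list alone, namely Ifi44, Bst2, Xaf1, Usp18, Isg15, Oas1a and Rtp4. DESeq2 called 5 members of this list. Replication-dependent histone genes shifted upwards with a median of 0.44 over 14 genes (adjusted p = 5.41e-06, and adjusted p = 0.147 with an estimated correlation), which was 0.24 with the Yam1 covariate and still called. Carry-over of non-polyadenylated RNA into these libraries was not excluded as a source of this shift. Most members were near the floor: of the 35 with counts, 6 averaged at least 1 CPM, and the list was not tested under the 5 CPM filter. Its most abundant member, H1f0 at 491 CPM, is a histone gene that is not replication-dependent. No histone gene was called over all genes by edgeR, 4 had an unadjusted p under 0.05, and DESeq2 called 1. Hist1h2bc was higher when adjusted over the list alone, at 26.0 ± 2.4 against 19.5 ± 1.3 CPM. Autophagy and lysosome genes had a median of 0.083 over 35 genes, with 0 called by edgeR over all genes or over the list alone, 9 at an unadjusted p under 0.05 and 0 called by DESeq2 (adjusted p = 0.00509, and adjusted p = 0.277 with an estimated correlation). Their median was 0.048 on library totals alone.

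The lists of protein synthesis, respiration and protein degradation genes were called higher with the preset correlation, by small amounts, and not with an estimated correlation. For the cytosolic ribosomal proteins, 72 of 74 log2 fold changes were positive, with a median of 0.13 (adjusted p = 8.28e-19, and adjusted p = 0.799 with an estimated correlation). Rps16 stood at 947 ± 75 CPM in HSPA1A and 792 ± 23 CPM in control libraries, a difference that did not pass the test. The nuclear oxidative phosphorylation genes had a median of 0.11 over 45 genes (adjusted p = 6.39e-06, and adjusted p = 0.876 with an estimated correlation). That median was 0.059 without HSPA1A replicate 1, 0.071 on library totals alone and 0.066 after a length and GC correction. With the Yam1 covariate it was 0.039, and the call ended (adjusted p = 0.108). Proteasome subunits had a median of 0.078 over 31 genes (adjusted p = 0.00111, and adjusted p = 0.882 with an estimated correlation). This call ended without control replicate 1 (adjusted p = 0.1004) or HSPA1A replicate 1 (adjusted p = 0.116), and with the Yam1 covariate (median 0.020, adjusted p = 0.592). The proteasome median was 0.041 on library totals alone, 0.046 without control replicate 1, 0.051 without HSPA1A replicate 3 and 0.13 without HSPA1A replicate 2. In each of these lists 0 genes were called by edgeR's quasi-likelihood test, over all genes or adjusted over the list alone. Unadjusted p-values under 0.05 were seen for 31 ribosomal, 12 respiratory and 2 proteasome genes, and DESeq2 called 1, 0 and 0.

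The cholesterol synthesis list was called lower with the preset correlation, with a median log2 fold change of -0.17 and 23 of 24 values negative (adjusted p = 4.31e-05), and not with an estimated correlation (adjusted p = 0.882). With the Yam1 covariate its median was 0.023, on the other side of 0. None of the 24 was called, over all genes or over the list alone, by edgeR; 2 had an unadjusted p under 0.05, and DESeq2 called 0. The list medians of the single HSPA1A libraries against the control mean were -0.32, 0.17 and -0.29 for replicates 1, 2 and 3. The list's median was -0.064 without HSPA1A replicate 1, where the call ended (adjusted p = 0.0781), -0.36 without replicate 2 and -0.085 without replicate 3. Extracellular matrix and fibrosis genes had a median of -0.031 over 36 genes (adjusted p = 0.0290, and adjusted p = 0.882 with an estimated correlation). Col8a1 was the 1 member called over all genes, and Mmp2 joined it when adjusted over the list alone. This list's call ended without control replicate 1 (median 0.0054, adjusted p = 0.437) or HSPA1A replicate 1 (median 0.011, adjusted p = 0.705). It also ended after a length and GC correction (median 0.013, adjusted p = 0.331) and with the Yam1 covariate (median 0.011, adjusted p = 0.651). The median was -0.066 on library totals alone, -0.0069 without HSPA1A replicate 3, -0.063 without control replicate 2 and -0.099 without HSPA1A replicate 2.

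**Figure D2:**
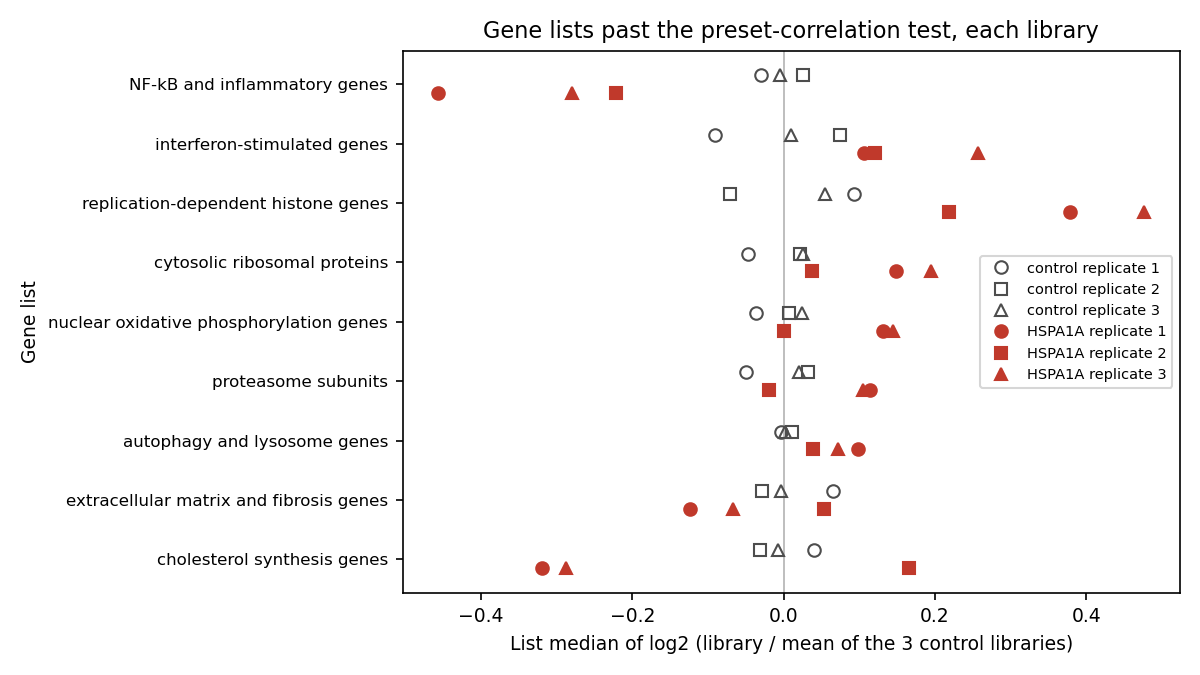
Median log2 ratio of each library to the mean of the 3 control libraries (x axis) over the members of the 9 gene lists called by camera with the preset correlation (y axis), 1 point per library, open for control and filled for HSPA1A. The inflammatory list lies below 0 in all 3 HSPA1A libraries, from -0.46 to -0.22, while the cholesterol list lies at 0.17 in HSPA1A replicate 2 and at -0.32 and -0.29 in replicates 1 and 3.

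The share of counts on Yam1 differed between libraries. It was 1.86%, 1.18% and 1.23% in control replicates 1 to 3 and 2.70%, 1.58% and 2.53% in HSPA1A replicates 1 to 3. The small noncoding RNAs Rmrp and Rn7sk, which were named after their values were seen, had log2 fold changes of 1.70 and 1.03 and did not pass the test (adjusted p = 0.0621 and 0.131, edgeR's quasi-likelihood test). DESeq2 called both (adjusted p = 4.13e-06 and 6.12e-05), and edgeR called Rmrp without HSPA1A replicate 2 (adjusted p = 0.000197). On library totals, the lowest HSPA1A library stood above the highest control library for Rmrp (3.90 against 2.31 CPM) and Rn7sk (12.7 against 10.6 CPM). The same held for the small noncoding RNA Rpph1 (1.13 against 0.756 CPM), also named after its values were seen.

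Genes of heart muscle and hypertrophy were of interest because the series concerns cardiac hypertrophy. In the hypertrophy and fetal gene programme 0 of 41 tested genes were called by edgeR, 3 had an unadjusted p under 0.05, and DESeq2 called 0. Without HSPA1A replicate 2, edgeR called 1 of the 41 higher, Fhl1, and 5 lower, among them Hdac5, Tgfb1 and Lif. The same fit called 1323 of all 12955 tested genes. The natriuretic peptide gene Nppb stood at 3.94 ± 0.55 CPM in control and 4.57 ± 0.81 CPM in HSPA1A libraries (log2 fold change 0.21, 95% interval -0.17 to 0.58). The skeletal actin gene Acta1 was at 0.447 ± 0.321 and 0.619 ± 0.065 CPM (log2 fold change 0.46, 95% interval -0.57 to 1.48). Myh7 had 1 read over all 6 libraries, and Nppa and Myh6 were not analysed here. Lif, a cytokine gene on this list, had the smallest p in it and a log2 fold change of -0.45 that did not pass the test over all genes in the fit of all 6 libraries. None of 17 sarcomere genes, 13 calcium handling genes and 17 cardiac transcription factor genes was called by edgeR or by DESeq2; 3, 3 and 0 had an unadjusted p under 0.05. Adjusted over the list alone, Jph2 was lower and Itpr2 higher in the calcium list, at log2 fold changes of -0.22 and 0.22.

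The heat shock and chaperone list was not called, with 26 of 46 log2 fold changes positive, a median of 0.0082 and values from -0.24 to 0.21. The list's camera adjusted p was 0.742, 0 members were called by edgeR or DESeq2, and 5 had an unadjusted p under 0.05. Hsf1, the gene of the main heat shock transcription factor, stood at 68.1 ± 2.9 CPM in HSPA1A and 76.9 ± 1.1 CPM in control libraries, which did not pass the test. Without HSPA1A replicate 2, edgeR called 5 of 47 members higher and 3 lower, with Hsf1 among the lower ones. The unfolded protein response list had 0 of 33 genes called and a median of -0.018 (camera adjusted p = 0.179). The splicing regulators had 0 of 52 called, by edgeR or DESeq2, with 2 at an unadjusted p under 0.05, a median of 0.014 and a camera adjusted p of 0.603. Without HSPA1A replicate 2, 4 of 33 unfolded protein response genes were called lower and 4 of 52 splicing regulators higher. Over all tested genes, that fit called 1323 of 12955. Counts per gene do not show splicing itself.

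The remaining lists were not called by camera. Immediate-early and stress kinase genes had 1 of 35 called, the lower Ier3, and the same 1 over the list alone. The p53 and apoptosis list had 0 of 34 called over all genes by edgeR, while Bcl2l11 and Fas were lower over the list alone, with log2 fold changes of -0.45 and -1.32. DESeq2 called both over all genes (adjusted p = 0.0319 and 0.0108). The NRF2 antioxidant list had 0 of 28 called over all genes by edgeR, with Gsta1, Gsta2 and Prdx1 higher and G6pdx lower over the list alone, and a camera adjusted p of 0.0565. DESeq2 called Gsta2 and Prdx1 higher over all genes (adjusted p = 0.0423 and 0.0477). The fatty acid oxidation list had 0 of 31 called over all genes, with Lpl higher over the list alone. In the S phase, G2 and mitosis, glycolysis and hypoxia, and mitochondrially encoded lists 0 of 36, 40, 36 and 15 genes were called, and none over the list alone. Markers of other cell types showed 0 called genes, of 11 for fibroblasts, 6 for endothelial cells, 6 for smooth muscle cells and pericytes and 2 for macrophages and leukocytes. Without HSPA1A replicate 2, 3 of the 11 fibroblast markers (Gsn, Col1a1 and Col3a1) and 1 of the 6 smooth muscle markers (Smtn) were called lower. The same fit called 1323 of all 12955 tested genes. Over the 24 lists with 0 called genes, 100 of 675 tested members had an unadjusted p under 0.05, and DESeq2 called 6. In the p53, calcium handling, glycolysis and hypoxia, G2 and mitosis, mitochondrially encoded and smooth muscle lists, the median, the mean and the direction of the camera test did not share a sign.

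**Figure D3:**
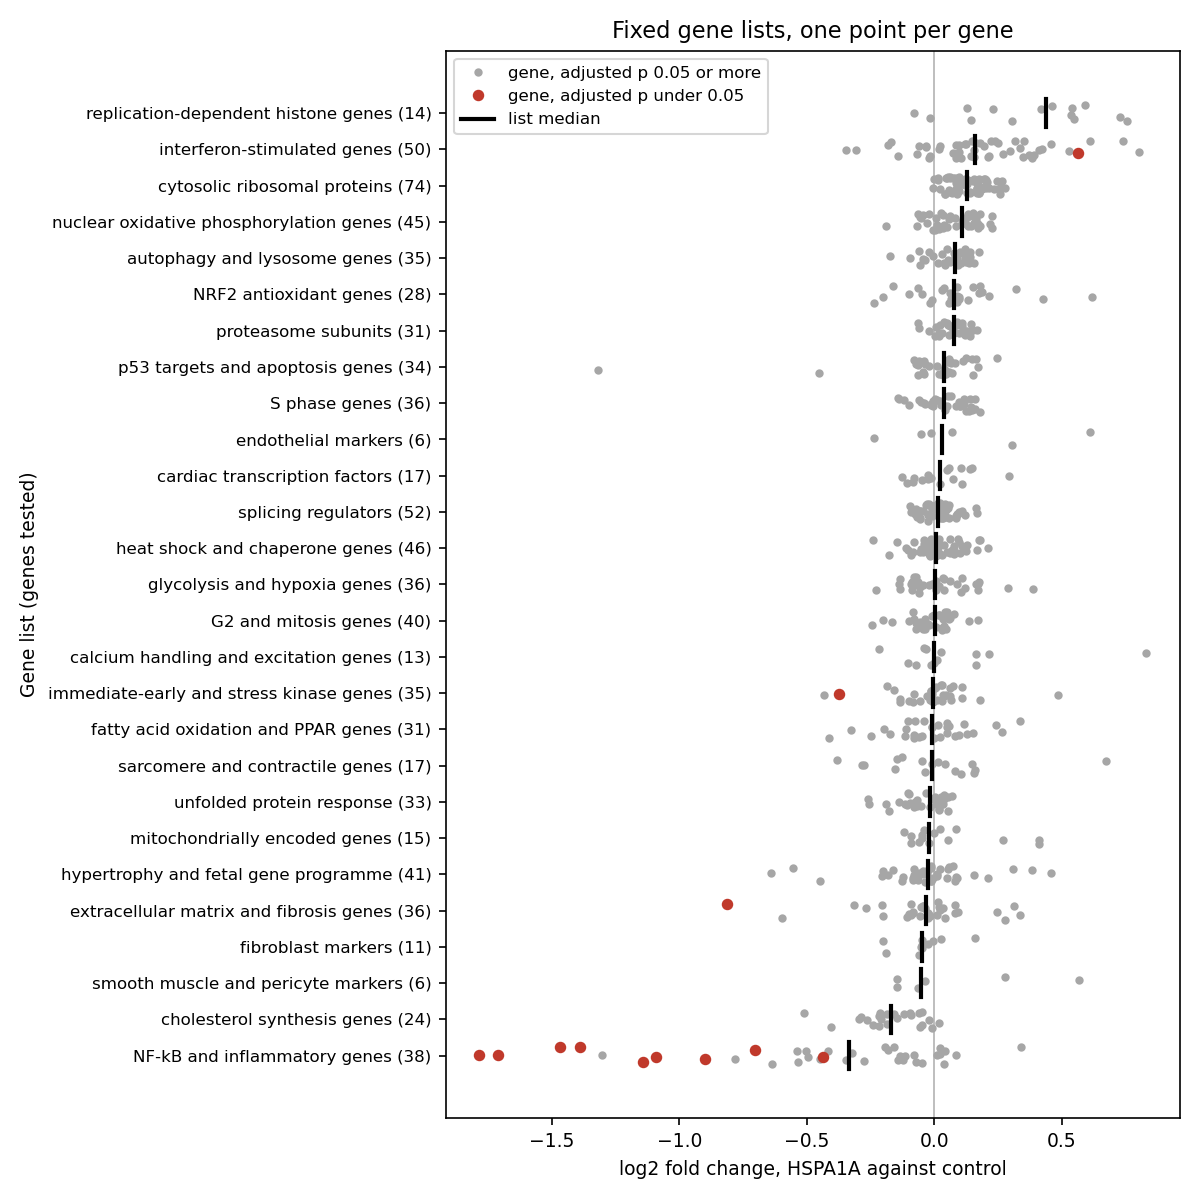
Log2 fold change of HSPA1A against control (x axis) for each tested gene of the 27 lists with at least 5 tested members (y axis), grey where the adjusted p was 0.05 or more and red where it was under 0.05. The black bar is the list median, which runs from -0.33 for the inflammatory list to 0.44 for the histone list.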

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

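The gene length and GC correction and the Yam1 covariate were chosen only after the results were seen; all other settings were planned. Of the 23 called genes, 7 stayed called in all 19 settings other than the 2-fold minimum (Cxcl1, Cxcl5, Ccl2, C3, Nfkbiz, Col8a1 and Zc3h12a), and all 23 kept their direction wherever they had a value. For genes higher in HSPA1A (3), the count was 1 with RLE size factors, 1 with library totals only, 1 with at least 5 CPM in 3 samples, 27 with DESeq2, 94 with no low-count filter, 5 with FPKM and a pseudocount of 1, 5 with a pseudocount of 0.1, 0 with a mean FPKM of at least 1 and 0 with at least a 2-fold change. For genes lower in HSPA1A (20), it was 41 with DESeq2, 111 with no low-count filter, 10 and 13 with FPKM at pseudocounts of 1 and 0.1, 8 with the Yam1 covariate and 7 with at least a 2-fold change. Leaving out one library at a time gave 0 to 683 genes higher and 10 to 640 lower, the highest of each without HSPA1A replicate 2. The fit without a filter tests more genes; for the other settings the cause was not tested. Of the fixed lists called (9), 1 remained with an estimated correlation, the inflammatory list, and fry called 3 (inflammatory, histone and autophagy lists). With the Yam1 covariate the cholesterol list reversed (median 0.023), and the oxidative phosphorylation, proteasome and extracellular matrix lists lost their calls (medians 0.039, 0.020 and 0.011); the length and GC correction ended the call of the extracellular matrix list (median 0.013).

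No consistent pairing by replicate number was seen. The deviations of same-numbered libraries correlated at -0.100, -0.0015 and 0.085, and only the libraries numbered 3 correlated best with each other. With 3 libraries per group, this cannot exclude that same-numbered libraries were handled together. With the replicate block, 3 genes were higher and 13 lower in HSPA1A, and 13 of these 16 were among the 23.

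The Hspa1a log2 fold change stayed positive in every setting that gave one, from 0.049 with FPKM and a pseudocount of 1 to 0.77 with the Yam1 covariate, and never passed the threshold; under the 5 CPM and mean FPKM filters it was not tested. None of the uncalled genes that reversed passed a threshold. With the Yam1 covariate the log2 fold changes were -0.25 for Acta1, -0.10 for Nppb, 0.23 for Cd14, 0.030 for Syvn1, -0.24 for mt-Rnr1 and -0.21 for mt-Rnr2. Leaving out libraries, Cd14 ranged from -0.22 without HSPA1A replicate 2 to 0.015 without control replicate 2 and 0.11 without HSPA1A replicate 3, and Hspa1b from -0.026 without HSPA1A replicate 2 to 0.23 without HSPA1A replicate 1; the cause was not tested. At about 0.5 CPM, Hspa1a and Acta1 had 86 and 81 reads in all, which limits any fold change for them.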

Other observations

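The tests of the interferon genes and of the human transcript, and the settings with a length and GC correction and with the Yam1 covariate, were chosen only after the results were seen. Without HSPA1A replicate 2, which lay apart from the other HSPA1A libraries, large parts of several gene groups were called by edgeR's quasi-likelihood test at an adjusted p under 0.05 in the remaining 5 libraries. Cholesterol synthesis genes were lower for 16 of 24, among them Cyp51, Nsdhl and Idi1, with 0 higher. Ribosomal protein genes were higher for 43 of 74, respiratory chain genes for 20 of 45, proteasome genes for 11 of 31 and S phase genes for 10 of 36, with 0 lower in each. The S phase genes included the replication helicase genes Mcm2 and Mcm3. Glycolysis and hypoxia genes were lower for 8 of 36, among them Eno1 and Slc2a1. The glycolysis list medians of HSPA1A replicates 1, 2 and 3 against the control mean were -0.25, 0.21 and -0.0035, and those of the S phase list 0.11, -0.14 and 0.13. The fibroblast markers Gsn, Col1a1 and Col3a1 were lower, 3 of 11, with a list median of -0.13, and the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were higher and mt-Atp6 lower. Of the interferon-stimulated genes 10 were higher and 1, Ifi27, lower, and 19 of 38 inflammatory genes were lower. Other lists moved both ways: the NRF2 antioxidant list had 4 of 28 higher and 7 lower, and the heat shock list 5 of 47 higher and 3 lower. That fit called 1323 of 12955 tested genes.

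Several genes of heart muscle were barely present in these HL-1 libraries. Over all 6 libraries Actn2 had 1 read, Myl2 3, Actc1 3, Tnni3 7 and Ryr2 11, while Tnnt2 averaged 40.6 CPM, Gata4 32.5 CPM, Nkx2-5 3.61 CPM and the intermediate filament gene Des 614 CPM. Genes typical of mesenchymal cells were high, with Vim at 5201 CPM, Col3a1 at 457 CPM and Col1a2 at 299 CPM. These levels are on library totals, and these genes were chosen after their values were seen.

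Inflammatory genes were lower in HSPA1A cells, with list medians below those of every control in all 3 libraries; the interferon, histone, autophagy and ribosomal lists had medians above every control in all 3. Of the 9 called list genes, 9 kept a 95% interval below 0 after the length and GC correction, and 9 with the Yam1 covariate, where 3 calls ended through wider errors. For these genes this argues against a length and GC bias, and against carry-over of non-polyadenylated RNA tracked by Yam1, as the whole cause. For the other members carry-over stays open, as the list median moved from -0.33 to -0.20. For all members a carry-over that followed the groups stays open, since Yam1 shares overlapped between the groups. The small noncoding RNAs Rmrp, Rn7sk and Rpph1 did not overlap, and they were not used as covariates. Carry-over also stays open for the histone list, whose median moved from 0.44 to 0.24 with the Yam1 covariate. A weaker response to transfection in every innate pathway would lower interferon genes too, yet 0% of the 7 interferon genes past an adjusted p of 0.05 over the list alone were lower, and 39 of all 50 tested had positive log2 fold changes. With an estimated correlation the interferon list was not called higher (camera adjusted p = 0.404), so a rise of the list itself is uncertain. The real grouping called 23 genes and the highest of the other splits 0; 1 of the 10 splits of the 6 libraries called as many, and 10 splits are too few for a share under 0.05. An effect of HSPA1A, the difference that the design names, stays among the open explanations as untested, as do differences between plasmid preparations.

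HSPA1A replicate 2 stood apart from replicates 1 and 3, and the small shifts of the ribosomal protein genes went with this. A length and GC bias was argued against as the whole cause of either. After that correction 938 genes were called without replicate 2, against 1323 before it, and the ribosomal median stayed at 0.115. The fall in calls leaves a partial contribution of that bias open. Carry-over of non-polyadenylated RNA stays open: 40.8% of 613 genes moved the same way in control replicate 1, a single library whose Yam1 share exceeded that of HSPA1A replicate 2, while that share was also higher in HSPA1A replicates 1 and 3 than in replicate 2, and the Yam1 covariate reversed the cholesterol list (median 0.023) but left the ribosomal list called (median 0.089). The ribosomal shift may be mainly one of 2 of the 3 libraries, since its median was 0.0372 in replicate 2, still above every control, against 0.149 and 0.195 in replicates 1 and 3. The 23 called genes moved the same way in replicate 2, where Cxcl1 stood at 42.9 CPM against 57.1 CPM in replicate 1. They were called with replicate 2 in the fit, so this agreement is built in and does not test a shared response. For the wider set called without replicate 2, a smaller shared response cannot be told apart from none or from an opposite shift. HSPA1A replicates 1 and 3 against 2 controls at a time called 613, 1095 and 603 genes, leaving out control replicates 1, 2 and 3. Of these, 55.5%, 38.1% and 41.3% moved the same way in replicate 2 against the control left out. Their median log2 differences in the direction of the call were 0.024, -0.042 and -0.039. For the number of lists called, 9, the other splits gave up to 12, and 6 of the 10 splits gave as many. This number therefore does not set the real grouping apart. Among the 9 lists the estimated correlation ran from 0.0077 for the autophagy list to 0.74 for the proteasome list, against the preset of 0.01. A preset that is too low can raise the number of lists called in any split. This cannot be told apart from a structure of the samples other than the groups, and neither was tested.

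No difference in mouse Hspa1a passed the test (log2 fold change 0.39, 95% interval -0.38 to 1.16), and at 86 reads in all an increase of over 2-fold lies within the interval. A human transcript that is not counted on mouse genes may be the reason that no larger difference was seen, and this cannot be told apart from low overexpression, because the level of the human transcript was not analysed here.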
